A study of Mus musculus with 18 samples.

How the data were processed

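Expression was measured in 18 samples of C2C12 cells, each on a one-colour array, with 6 samples per shRNA group as the sample titles give them. Per the labels' protocols, total RNA was extracted with Trizol and column-purified, and biotin-labelled targets were hybridised. The deposited values are log2 expression values per probe set; per the submitters' processing notes they were made with RMA and Partek, whose versions, settings and genome build are not given in the sources used here. RMA corrects background, quantile-normalizes arrays and summarizes the probes of a set, which makes the arrays alike in distribution and compresses differences of dim genes. The values ran to at most 13.7 on the log2 scale, none was missing, and all columns belonged to samples of this series. Scan dates and batches are not given in the sources used here, so no batch was tested.

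Probe sets were named through the platform annotation supplied with the table: 23521 probe sets had 1 gene symbol, 1814 several and 16010 none. Symbols were checked through Entrez identifiers against the RefSeq gene table of mouse assembly GRCm38.p6, which held 23328 of the singly named probe sets and changed 0 symbols. No coordinates are given because no genome build is named with the values; the same table was used only for names and for which genes are neighbours. Probe sets with several symbols or none were left out of gene tests. For each of the 22180 genes the probe set with the highest mean over all 18 arrays was used; 1082 genes had more than 1, and other probe sets of named genes are given where they disagreed. The level of 1394 olfactory and vomeronasal receptor genes served as a guide to background: 58.7% of genes exceeded their 95th percentile of 5.47.

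All 18 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per group, no covariate and default empirical Bayes moderation, leaving 15 residual degrees of freedom. The 3 contrasts were Nup210 against control shRNA, Mef2c against control shRNA and Nup210 against Mef2c shRNA, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a single gene is from this limma fit unless another test is named, and "adjusted over the list alone" means that the adjustment covered the members of a list. The targeted genes were also compared by two-sided exact permutation tests over all 924 splits. A total of 31 gene lists with 669 entries, 615 of them measured, were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 31 lists within a contrast, and again with an estimated correlation. With the preset, camera called 2 lists higher and 14 lower for Nup210 shRNA, 4 and 13 for Mef2c shRNA, and 6 and 4 between them. With an estimated correlation it called 0 and 0, 1 and 6, and 0 and 0; the 7 that held were mitosis, S phase, cholesterol synthesis, unfolded protein response, focal adhesion, TGF-beta and BMP response and adipocyte markers for Mef2c shRNA. The self-contained test fry, which asks whether members move in 1 direction on balance and does not compare a list with other genes, called 17, 20 and 18 lists.

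The tests, the lists, the rule for named genes and all alternatives but a pair were fixed before the data were examined. The rule named, per comparison with control, the targeted genes, the 6 largest rises and 6 largest falls among called genes with all 6 arrays on the same side of the control mean, and the 2 largest changes of each list with at least 3 called members, leaving out predicted genes and small RNAs. It also named the 4 largest differences per direction between the shRNA groups, 5 genes per direction changed in both, 3 of each opposite kind, and Trip6, Mef2a, Mef2d, Myod1 and Myog. Overlaps of calls were set beside independent lists, beside 100 simulated pairs of unchanged groups sharing the controls, and beside all 20 splits of the controls.

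The fit was tested on simulated data with known answers on 22180 genes. For Nup210 against control shRNA it recovered 24.2% of genes changed by 0.25 on the log2 scale, 77.6% at 0.5 and 97% at 1, with 3.62% of calls false; for Mef2c against control shRNA it recovered 25.8%, 82.1% and 97%, with 4.86% false. In the first comparison camera gave an unadjusted p under 0.05 to 2 of 100 unchanged lists. The simulated genes were drawn independently, so this does not test camera on lists whose members correlate. The estimated correlation was 0.63 for cholesterol synthesis and 0.48 for mitosis. Alternatives were the replicate number as a block, only the groups compared in the fit, renewed quantile normalization, median centring, leaving out dim genes, averaging or testing all probe sets of a gene, a trended robust prior, array weights, stricter thresholds, an unequal-variance test per gene without moderation, an estimated correlation in camera, and leaving out each array in turn. Added after seeing the data were fits without the 3 arrays of lowest weight (under 0.75, with weights from 0.62 to 1.44 over all arrays) and without control arrays 4 and 6. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.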

Results

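Gene expression was measured on 18 one-colour arrays of C2C12 cells, a mouse myoblast line that fuses into multinucleate myotubes when growth serum is withdrawn. Cells were grown in 20% fetal bovine serum, moved to 2% horse serum to start differentiation, infected 36 h later with a lentivirus carrying a short hairpin RNA (shRNA), and harvested 48 h after that. The arrays formed 3 groups of 6: a scrambled control shRNA, an shRNA against Nup210, which encodes a membrane glycoprotein of the nuclear pore, and an shRNA against Mef2c, which encodes a transcription factor of the muscle programme. The design allows the genes that differ with the Nup210 shRNA label to be set beside those that differ with the Mef2c shRNA label. Values were on the log2 scale, and 22180 genes were tested. Array medians ran from 5.48 to 5.57, and arrays within a group correlated at 0.991 to 0.995 across genes. The 6 arrays per group limit the precision, with a typical standard error (SE) of 0.080 for a log2 difference. Nothing in the labels says that the arrays of a group came from separate cultures, so all p-values measure the spread between these samples, which may be technical.

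Mef2c was lower in the Mef2c shRNA arrays than in any control array. Its brighter probe set averaged 7.91 ± 0.21 (SD, n = 6) against 10.39 ± 0.16 in controls, which is 17.9% of the control level. The exact two-sided permutation test gave p = 0.00216 for n = 6 against 6, the smallest p that the 924 splits allow. The exact p became 0.00648 after Benjamini-Hochberg adjustment over the 6 tests of targeted probe sets. The dimmer probe set fell by 1.86 on the log2 scale, to 27.6% of control, with the same exact p. In the Nup210 shRNA arrays Mef2c stood at 94.2% of control on its brighter probe set, a difference within the spread between replicates (exact permutation p = 0.422). Its dimmer probe set stood at 84.8% there (exact permutation p = 0.104, adjusted p = 0.125). Nup210, read by a single probe set, averaged 5.65 ± 0.11 in the Nup210 shRNA arrays and 5.75 ± 0.09 in controls. That is 93.1% of control, and the difference did not exceed the spread between replicates (exact permutation p = 0.0801, adjusted p = 0.12). In the Mef2c shRNA arrays Nup210 averaged 5.88 ± 0.12, or 109% of control (exact permutation p = 0.0411, adjusted p = 0.0822). The probe set lay near background: its mean of 5.76 exceeded the means of 96.5% of 1394 olfactory and vomeronasal receptor genes, a class with little expression outside sensory tissue, whose 95th percentile was 5.47. Control array 6 was low for Nup210 (5.57 against 5.75 to 5.81 in the other controls). Without it the log2 difference was -0.14 in place of -0.10. With all controls included, the arrays labelled Nup210 shRNA carry no mRNA measurement that clearly separates them from controls at this gene. They are called by their label below.

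**Figure D1:**
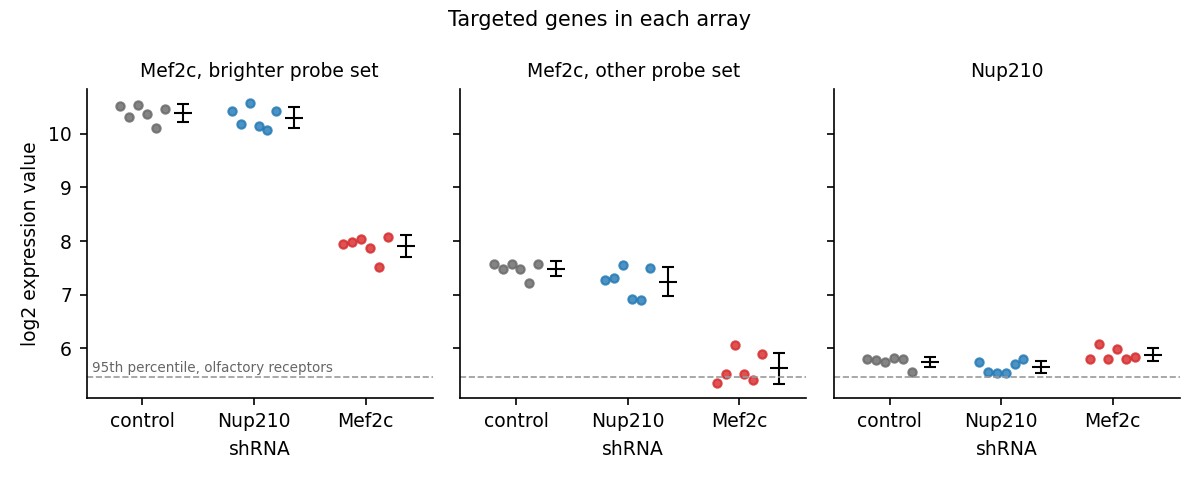
Each point is an array, with log2 expression on the vertical axis and the shRNA group on the horizontal axis; bars give the mean ± SD of 6 arrays, and the dashed line marks 5.47, the 95th percentile of olfactory and vomeronasal receptor genes. All 6 Mef2c shRNA arrays lie below every control for both Mef2c probe sets, while the Nup210 values of the 3 groups lie close to the dashed line.

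In the Nup210 shRNA arrays, 2 mast cell proteases were called higher from levels below background, and a regulator of cell death led the genes that fell. Mcpt1 stood at 6.99 against 5.18 in controls (limma adjusted p = 1.45e-05), the control level lying below the receptor-gene background, so that the size of its log2 difference of 1.81 ± 0.20 (SE) is uncertain. Mcpt4 was called higher (adjusted p = 0.000726) with both groups below that background, which leaves its change unmeasured. Sfrp4, a secreted modulator of Wnt signalling, rose 2.07-fold, the serpin Serpinb6b 2.06-fold, the prostaglandin-degrading enzyme Hpgd 1.98-fold and the carbonic anhydrase Car2 1.88-fold. Dap (death-associated protein) fell to 0.363 of control (log2 change -1.46 ± 0.066 SE, adjusted p = 3.39e-10). Padi2, a peptidyl arginine deiminase, fell by 1.11 on its brighter probe set, while its other probe set changed by -0.09. Hephl1 fell by 1.11, Slc44a4 by 1.04, the epidermal transcription factor Grhl3 by 1.02 and Fam180a by 0.997 on the log2 scale. In each of these 12 genes all 6 Nup210 shRNA arrays lay on the same side of the control mean. In limma's test with Benjamini-Hochberg adjustment, 676 genes rose and 1133 fell; 24 of the rises and 67 of the falls reached 1.5-fold, and 4 (Mcpt1 and Mcpt4 among them) and 5 reached 2-fold. With each array centred on its median the split was 395 higher and 1177 lower, so that 74.9% of called genes fell in place of 62.6%. Renewed quantile normalization moved the split the other way, with 802 higher and 1072 lower, so that 57.2% fell. Arrays 2, 4 and 5 of this group had the lowest weights of all 18, and in a fit without them, added after seeing the data, 153 genes rose and 410 fell, with 541 of the 1809 calls kept. The calls of Grhl3 (adjusted p = 0.0611) and Fam180a (adjusted p = 0.154) were among those lost. Without control arrays 4 and 6, also added after seeing the data, there were 379 rises and 724 falls.

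Contractile and calcium-handling lists were called lower in the Nup210 shRNA arrays, though fewer than 0.5 of each list's members passed and no list passed with an estimated correlation. Of 24 measured genes of excitation-contraction coupling, 11 fell and none rose (14 fell and 2 rose when adjusted over the list alone), with a median log2 change of -0.16 (camera adjusted p = 1.26e-07, and adjusted p = 0.0792 with an estimated correlation). They included Casq1, the calcium buffer of the sarcoplasmic reticulum (-0.82 ± 0.22 SE, adjusted p = 0.0238), and Hrc, a histidine-rich calcium-binding protein of the same store (-0.58 ± 0.087, adjusted p = 0.000319). The Casq1 call was lost without Nup210 shRNA array 2 (adjusted p = 0.0567), 4 (0.0618) or 5 (0.0542), or without control array 3 (0.0598). Of 17 thick filament and M-line genes, 7 fell (9 adjusted over the list alone), among them the slow myosin heavy chain Myh7 (-0.52 ± 0.052, adjusted p = 6.04e-06) and the myosin light chain kinase Mylk2 (-0.52 ± 0.085, adjusted p = 0.000685). As a list they had an adjusted p of 1.76e-07, and adjusted p = 0.0792 with an estimated correlation. Of 37 thin filament and Z-disc genes 9 fell (10 adjusted over the list alone), with the pointed-end capper Tmod1 at -0.58 ± 0.055 (adjusted p = 3.17e-06) and the slow troponin Tnnt1 at -0.37 ± 0.086 (adjusted p = 0.00996). Camera gave the list an adjusted p of 2.27e-05, and adjusted p = 0.154 with an estimated correlation. Of 25 published MEF2 targets, 10 fell, including Hrc, and Jun rose by 0.55 (11 and 1 adjusted over the list alone; camera adjusted p = 9.71e-06, and adjusted p = 0.154 with an estimated correlation). The list shares genes such as Myom1 and Smyd1 with the filament lists. Myoblast fusion genes had 7 falls and 1 rise, of Arhgap26, among 20 (the same adjusted over the list alone), led by the membrane repair protein Myof (-0.45 ± 0.040, adjusted p = 1.55e-06) and Dock5 (-0.37 ± 0.079, adjusted p = 0.00549). For the list as a whole the adjusted p was 3.3e-05, and adjusted p = 0.0653 with an estimated correlation. Dystrophin complex and costamere genes had 4 falls and 2 rises among 21 (8 and 2 adjusted over the list alone; adjusted p = 0.000687, and adjusted p = 0.112 with an estimated correlation). Sgcd fell by 0.50, and Dag1, Sgca and Dysf fell by 0.24, 0.24 and 0.23, while Lama2 rose by 0.35 and Tln2 by 0.15; Arhgap26, Dag1, Sgca, Dysf and Tln2 were chosen after their values were seen. Neuromuscular junction genes had 3 falls among 12, of Dok7, Chrnb1 and Rapsn, the last chosen after its value was seen (3 adjusted over the list alone). The list's adjusted p was 0.00487, which became 0.0792 with an estimated correlation and 0.0549 with dim genes left out. The Dok7 call was lost without Nup210 shRNA array 5 (adjusted p = 0.0525) or control array 1 (0.0511) or 3 (0.0531). The Chrnb1 call was lost without Nup210 shRNA array 1 (0.0654), 3 (0.0552), 4 (0.0529) or 5 (0.0533) or control array 1 (0.0563), 2 (0.0612), 4 (0.0723) or 6 (0.0598). Without Nup210 shRNA arrays 2, 4 and 5 fewer members of each of these lists were called. Excitation-contraction coupling then had 5 falls (camera adjusted p = 9.43e-05), thick filament genes 4 (0.000264), thin filament genes 2 (0.00183), MEF2 targets 5 and 1 rise (0.00053) and fusion genes 5 (0.000488). Dystrophin complex (0.0198) and neuromuscular junction genes (0.0077) had no called member. The calls of Casq1 (adjusted p = 0.391), Tnnt1 (0.263), Dock5 (0.204), Sgcd (0.124), Lama2 (0.0845), Dok7 (0.323) and Chrnb1 (0.145) were lost there, that of Tnnt1 also in the unequal-variance test (0.102), and those of Dok7 (0.0925) and Chrnb1 (0.163) without control arrays 4 and 6.

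In the Nup210 shRNA arrays 3 transcription factors of the muscle lineage rose and 1 fell. Myf5 rose by 0.66 ± 0.087 (SE; adjusted p = 9.48e-05) and Myod1 by 0.26 ± 0.051 (adjusted p = 0.00266), Mrtfb by 0.12 (chosen after its value was seen), and Mef2d fell by 0.17 ± 0.044 (adjusted p = 0.0163). Those were the changes among 18 such genes, or 6 rises and 1 fall adjusted over the list alone, and the list as a whole did not pass camera's test (adjusted p = 0.145). Without Nup210 shRNA arrays 2, 4 and 5 the calls of Myod1 (adjusted p = 0.105) and Mef2d (adjusted p = 0.166) were lost, and without control arrays 4 and 6 that of Mef2d (adjusted p = 0.0573). Myog changed by 0.01 (adjusted p = 0.959), Mef2a by 0.05 (adjusted p = 0.615) and Trip6, a LIM-domain adaptor protein, by 0.08 (adjusted p = 0.25), none past the test.

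Lists of cholesterol synthesis, glycolysis and focal adhesion were also called lower in the Nup210 shRNA arrays, and none of them passed with an estimated correlation. Of 17 cholesterol synthesis genes 9 fell (15 adjusted over the list alone) with a median log2 change of -0.23 (camera adjusted p = 1.33e-11, and adjusted p = 0.112 with an estimated correlation). Ebp, a sterol isomerase, fell by 0.63 ± 0.089 SE (adjusted p = 0.000202). Insig1, which retains the sterol sensor in the endoplasmic reticulum, fell by 0.46 ± 0.12 (adjusted p = 0.021), a call lost without Nup210 shRNA array 5 (adjusted p = 0.0524) or control array 6 (adjusted p = 0.0509). The list's mean in single Nup210 shRNA arrays ran from -0.47 to -0.15, and without arrays 2, 4 and 5 of this group 1 of its genes fell, with a median of -0.18 and an adjusted p of 1.34e-05. Glycolysis and glycogen genes had 6 falls among 17 (9 adjusted over the list alone; adjusted p = 9.71e-06, and adjusted p = 0.0792 with an estimated correlation), led by the muscle phosphoglycerate mutase Pgam2 (-0.46 ± 0.081, adjusted p = 0.00119) and the glycogen phosphorylase Pygm (-0.41 ± 0.073, adjusted p = 0.00136). Focal adhesion genes had 9 falls and 2 rises, of Zyx and Tes, among 27 (16 and 3 adjusted over the list alone), with the integrin Itga6 at -0.41 ± 0.087 (adjusted p = 0.00561). The other probe set of Tes changed by 0.00. The list passed (adjusted p = 1.29e-05, and adjusted p = 0.0792 with an estimated correlation). The TGF-beta and BMP list had 5 falls among 19 (6 adjusted over the list alone; adjusted p = 0.000557, and adjusted p = 0.0792 with an estimated correlation), which were Cnn1, Tagln, Ltbp2, Tgfb1 and Ccn1, the last 3 chosen after their values were seen. Tagln lost its call without Nup210 shRNA array 2 (adjusted p = 0.0803), 3 (0.0627) or 5 (0.0875), or control array 1 (0.0525), 2 (0.0558), 4 (0.0779) or 6 (0.085). Cnn1 and Tagln with Smtn were also the 3 falls among 10 smooth muscle markers (4 adjusted over the list alone; adjusted p = 0.00381, and adjusted p = 0.154 with an estimated correlation). Extracellular matrix genes had 8 falls and 2 rises among 33 (9 and 2 adjusted over the list alone), with Col6a3 at -0.42; Col3a1 at 0.38 and Dcn at 0.26 were the rises. The list's adjusted p of 0.0377 became 0.333 with an estimated correlation. That call was also lost without Nup210 shRNA array 2 (adjusted p = 0.0854), 4 (0.0809) or 5 (0.0622), without control array 1 (0.0538) or 3 (0.0756), on renewed quantile normalization (0.0571) and with dim genes left out (0.112). Without Nup210 shRNA arrays 2, 4 and 5 the matrix list had 1 fall and 2 rises (0.558), glycolysis 3 falls (0.000943), TGF-beta and BMP response 2 (0.00861), smooth muscle markers 1 (0.0077) and focal adhesion none (0.000689). The calls of Insig1 (adjusted p = 0.387), Itga6 (0.0722), Tes (0.0635), Cnn1 (0.135), Tagln (0.362), Col6a3 (0.238) and, narrowly, Pygm were lost there. Those of Insig1 (0.112), Itga6 (0.0516), Tes (0.0798), Cnn1 (0.129), Tagln (0.201) and Col6a3 (0.0657) were also lost without control arrays 4 and 6. Zyx, Smtn and Dcn were chosen after their values were seen.

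Of the remaining lists of the Nup210 shRNA arrays, p53 targets and interferon response genes were called higher, the unfolded protein response was called lower, and the others did not pass. Among 20 p53 targets 7 rose and Ei24, Plk3 and Rrm2b fell (11 and 3 adjusted over the list alone), with Trp53inp1 at 0.55 ± 0.080 SE (adjusted p = 0.00023) and Zmat3 at 0.47 ± 0.085 (adjusted p = 0.00174). As a list they had an adjusted p of 0.0103, and adjusted p = 0.264 with an estimated correlation. Without arrays 2, 4 and 5 of this group the p53 list (adjusted p = 0.148), Zmat3 (0.075), Aaas (0.326), Gle1 (0.212), Lmnb2 (0.0894) and Trim63 (0.054) were no longer called. Of 32 interferon response genes Ifit1 and Parp14 rose (2 adjusted over the list alone; chosen after their values were seen), with a list adjusted p of 0.00351, which became 0.0792 with an estimated correlation and 0.0648 with dim genes left out. Of 24 genes of the unfolded protein response Xbp1 fell by 0.31 and Dnajb11 by 0.25 (3 falls adjusted over the list alone; both chosen after their values were seen), and the list's adjusted p of 0.00508 became 0.264 with an estimated correlation and 0.0634 without control arrays 4 and 6. The nuclear pore complex list had a rise of Aaas and falls of Seh1l and Gle1 among 25 (1 and 3 adjusted over the list alone; list adjusted p = 0.888). The Gle1 call was lost without any Mef2c shRNA array, Nup210 shRNA array 1, 2, 4 or 6, or control array 1, 2, 3 or 5, with adjusted p from 0.0501 to 0.109. The nuclear envelope and lamina list had a rise of Syne1 and falls of Lmnb2 and Syne3 among 19 (1 and 2 adjusted over the list alone; list adjusted p = 0.875). Its median of 0.0040 and mean of -0.012 had opposite signs. No mitosis gene of 27 was called (adjusted p = 0.151), but leaving out Nup210 shRNA array 6 (adjusted p = 0.0241), control array 3 (0.00456) or control array 5 (0.0212) called the list lower. Without control arrays 4 and 6 its median turned to 0.053 (adjusted p = 0.153). In S phase Mcm7 rose and Mcm2 fell among 26 genes (1 and 1 adjusted over the list alone; list adjusted p = 0.309). The S phase list was called higher without control array 6 (0.0411) and without control arrays 4 and 6 (0.00281). Among 23 reserve and progenitor cell markers Id3 rose and Sdc4 fell (1 and 1 adjusted over the list alone; list adjusted p = 0.242). In oxidative phosphorylation Uqcrc1 rose among 28 genes (1 adjusted over the list alone; list adjusted p = 0.134, and 0.0366 or 0.0455 without Nup210 shRNA array 4 or 5, and 0.00109 without arrays 2, 4 and 5). The NF-kB and inflammatory list (adjusted p = 0.162; Ccl7 rose, Lif fell) did not pass, nor did the atrophy, ubiquitin and autophagy list (adjusted p = 0.732), where Gabarapl1 and Sqstm1 rose and Trim63 and Trim55 fell. Among reference genes (adjusted p = 0.875) Polr2a rose and Tbp fell. These lists had 1 and 1, 4 and 3, and 1 and 1 rises and falls adjusted over the list alone. Markers of fibroblasts (list adjusted p = 0.429; Dcn rose, S100a4 fell) and neural cells (0.567; Tubb3 fell) did not pass, with 1 rise and 2 falls and with 1 fall adjusted over the list alone. No marker of osteoblasts (0.799), adipocytes (0.541) or macrophages (0.652) was called, also when adjusted over the list alone. The genes this paragraph names, other than Trp53inp1, Zmat3, Aaas, Gle1, Lmnb2, Syne3, Gabarapl1 and Trim63, were chosen after their values were seen.

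In the Mef2c shRNA arrays the targeted gene showed the largest fall, followed by a zinc transporter, a growth factor and an enzyme of methionine salvage. Mef2c changed by -2.48 ± 0.10 SE (limma adjusted p = 2.8e-11). Slc30a5, a zinc transporter, fell to 0.323 of control (-1.63 ± 0.055, adjusted p = 2.14e-12) and the growth factor Igf2 to 0.372 (-1.43 ± 0.097, adjusted p = 4.77e-08). The methionine salvage enzyme Mtap fell to 0.406 (-1.30 ± 0.047, adjusted p = 3.17e-12) and the peptidyl-prolyl isomerase Ppic to 0.461 (-1.12 ± 0.045, adjusted p = 1.59e-11). Ccn2, a matricellular growth factor, fell by 1.13 on its brighter probe set and changed by -0.15 on its dim one. The serpin Serpinb9e rose 2.07-fold, lipoprotein lipase, Lpl, 1.91-fold (log2 change 0.22 on its dim probe set) and Car2 1.86-fold. The vacuolar ATPase subunit Atp6v0d2 rose by 1.25 ± 0.19 on the log2 scale from a control level of 5.08, below the receptor-gene background, so that the size of this difference is uncertain. The ribonuclease Rnase1 (5.45 against 4.44) and the odorant receptor Olfr823 (2.82 against 1.93) were called higher with both groups below that background. For each of these 12 genes all 6 Mef2c shRNA arrays lay on the same side of the control mean. In limma's test 963 genes rose and 1423 fell; 34 rises and 124 falls reached 1.5-fold, and 3 (Atp6v0d2 and Rnase1 among them) and 7 reached 2-fold. With each array centred on its median 625 rose and 1428 fell, so that 69.6% of called genes fell in place of 59.6%. On renewed quantile normalization 1125 rose and 1396 fell, so that the share that fell was 55.4%. Without control arrays 4 and 6 there were 537 rises and 883 falls.

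Cell cycle genes fell in the Mef2c shRNA arrays. Of 27 mitosis genes 24 fell and none rose (26 fell adjusted over the list alone), with a median log2 change of -0.72 (camera adjusted p = 6.27e-35, and 0.0205 with an estimated correlation). The kinetochore gene Ndc80 fell by 0.97 ± 0.11 SE (adjusted p = 8.74e-06) and the spindle gene Hmmr by 0.88 ± 0.088 (adjusted p = 3.55e-06). Of 26 S phase genes 18 fell (25 adjusted over the list alone; median -0.29, adjusted p = 2.42e-20, and 0.0205 with an estimated correlation), with the replicative helicase subunit Mcm3 at -0.51 ± 0.082 (adjusted p = 0.000413) and the origin-loading factor Cdc6 at -0.48 ± 0.089 (adjusted p = 0.0013). Control arrays spread widely for the mitosis list, from -0.21 to 0.23 around their mean with arrays 4 and 6 highest, and the Mef2c shRNA arrays lay between -0.74 and -0.55. Without control arrays 4 and 6, 22 mitosis genes fell, with a median of -0.61.

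Cholesterol synthesis and the unfolded protein response fell in the same arrays. Of 17 cholesterol synthesis genes 14 fell (14 adjusted over the list alone; median -0.45, camera adjusted p = 4.93e-18, and 0.0496 with an estimated correlation). Insig1 fell by 0.91 ± 0.12 SE (adjusted p = 4.89e-05) and the lanosterol synthase Lss by 0.73 ± 0.081 (adjusted p = 9.25e-06). Of 24 genes of the unfolded protein response 13 fell (16 adjusted over the list alone; median -0.17, adjusted p = 3.79e-12, and 0.0205 with an estimated correlation), led by the endoplasmic reticulum chaperone Hyou1 (-0.49 ± 0.040, adjusted p = 4.62e-07) and the asparagine synthetase Asns (-0.35 ± 0.059, adjusted p = 0.000512).

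**Figure D2:**
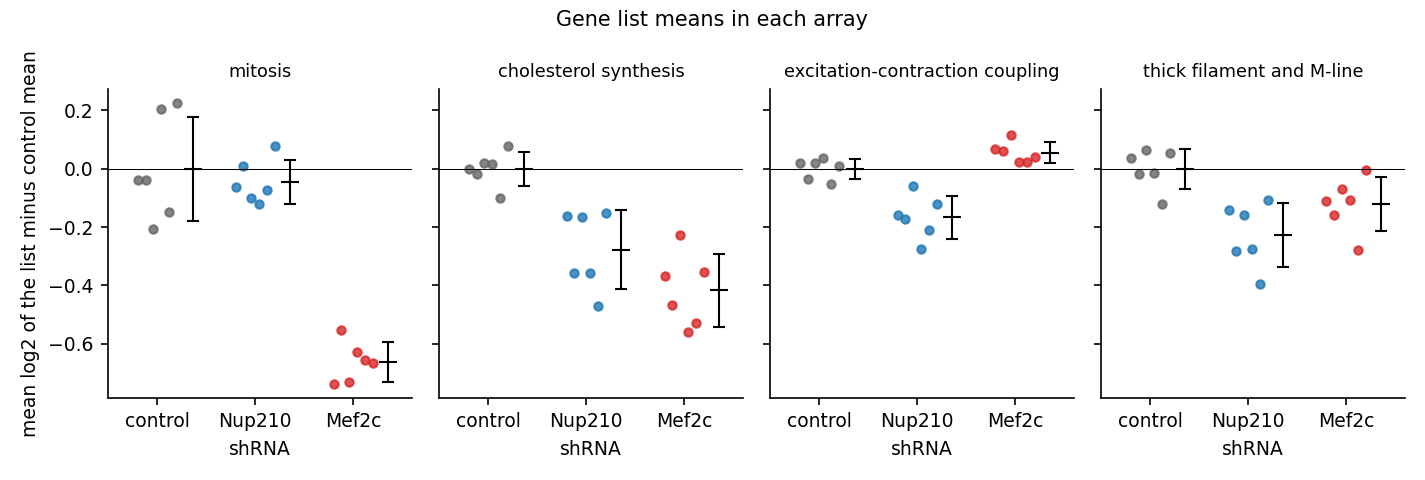
Each point is an array, with the mean log2 value of a gene list minus its control mean on the vertical axis and the shRNA group on the horizontal axis; bars give the mean ± SD of 6 arrays. For mitosis the Mef2c shRNA arrays lie between -0.74 and -0.55 and the controls between -0.21 and 0.23; for excitation-contraction coupling the Nup210 shRNA arrays lie between -0.27 and -0.06.

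The thin filament list was called lower in the Mef2c shRNA arrays, with most members not past the test, while excitation-contraction coupling genes did not pass as a list. Of 37 thin filament and Z-disc genes 10 fell and Pdlim3, chosen after its value was seen, rose (11 and 2 adjusted over the list alone), with the Z-disc crosslinker Actn2 at -0.67 ± 0.069 SE (adjusted p = 4.18e-06) and Tcap, which caps titin at the Z-disc, at -0.71 ± 0.17 (adjusted p = 0.0111, and 0.0711 without control arrays 4 and 6). Camera gave the list an adjusted p of 4.47e-05, and adjusted p = 0.183 with an estimated correlation. Of 17 thick filament genes Mybpc1, Myh7 and Myh3 fell (4 falls and 1 rise adjusted over the list alone; Myh3 chosen after its value was seen), with a list adjusted p of 0.0212, and adjusted p = 0.399 with an estimated correlation. That call was lost without Mef2c shRNA array 5 (adjusted p = 0.0911), on renewed quantile normalization (0.0523) and with dim genes left out (0.239). Excitation-contraction coupling genes had 3 rises and 4 falls among 24 (6 and 4 adjusted over the list alone) and did not pass as a list (adjusted p = 0.3). Casq1 fell by 0.95 ± 0.22 (adjusted p = 0.00695). Sln, a regulator of the calcium pump, was called higher (log2 difference 0.62 ± 0.10, adjusted p = 0.000538) at a level of 4.76. That level is below the receptor-gene background, so that the size of the Sln difference is uncertain. Jph1, Atp2a2 and Srl also fell and Ryr3 and Tmem38a also rose, all chosen after their values were seen. Of 25 published MEF2 targets Myoz2, Xirp1 and Smyd1 fell and none rose (4 falls adjusted over the list alone; Smyd1 chosen after its value was seen). The Myoz2 call was lost without control arrays 4 and 6 (adjusted p = 0.087). The list did not pass (adjusted p = 0.302), and its median of 0.013 and mean of -0.034 had opposite signs. Myoblast fusion genes had 4 falls among 20 (5 adjusted over the list alone), with the adhesion genes Jam2 at -0.54 and Cdh15 at -0.33, Adam12 at -0.31 and Il4ra at -0.17, the last pair chosen after their values were seen. The fusion list's adjusted p of 0.0263 became 0.157 with an estimated correlation, 0.0841 with dim genes left out, 0.0514 without Mef2c shRNA array 3 and 0.0618 on renewed quantile normalization. Dystrophin complex genes had 5 falls and 2 rises among 21 (7 and 4 adjusted over the list alone), with Sgcd at -0.64 and Dag1 at -0.54. Ankrd2, Sspn and Fhl1 fell by 0.51, 0.48 and 0.36 and Lama2 and Sgcb rose by 0.25 and 0.15, chosen after their values were seen. Their list adjusted p of 0.044 became 0.33 with an estimated correlation and 0.13 on renewed quantile normalization. It was lost without Nup210 shRNA array 3 (0.0503), Mef2c shRNA array 3 (0.0632) or 5 (0.1), or control array 1 (0.0504), 3 (0.0567), 4 (0.054) or 6 (0.0833), with dim genes left out (0.286), with probe sets averaged (0.0586), without Nup210 shRNA arrays 2, 4 and 5 (0.0599) and without control arrays 4 and 6 (0.119). Neuromuscular junction genes had 2 rises among 12, Chrng at 0.31 and Chrnd at 0.16 (chosen after their values were seen; 2 rises and 1 fall adjusted over the list alone; list adjusted p = 0.54).

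Among 18 myogenic transcription factors of the Mef2c shRNA arrays, 2 rose and 3 fell (3 and 6 adjusted over the list alone; list adjusted p = 0.0841). Myf6 fell by 0.52 ± 0.082 SE (adjusted p = 0.000294), Tcf12 by 0.38 (chosen after its value was seen) and Mef2d by 0.16 (adjusted p = 0.0195), a call lost without Mef2c shRNA array 2 (adjusted p = 0.0506) and without control arrays 4 and 6 (0.0655). Eya1 rose by 0.49 ± 0.10 (adjusted p = 0.0031) and Myf5 by 0.33 (adjusted p = 0.0192). Myog changed by -0.16 ± 0.052 and missed the threshold at an adjusted p of 0.0506, which it passed without Nup210 shRNA array 4 (0.0434), Mef2c shRNA array 6 (0.0153), control array 3 (0.0438) or control array 5 (0.0482). Myog also passed on median centring (0.0376), with dim genes left out (0.0166), with a trended robust prior (0.0111), with array weights (0.0336) and with the replicate number as a block. Myod1 changed by 0.09 (adjusted p = 0.346), Mef2a by -0.01 (adjusted p = 0.916) and Trip6 by 0.05 (adjusted p = 0.489). Of 23 reserve and progenitor cell markers 2 rose and 6 fell (4 and 8 adjusted over the list alone; list adjusted p = 0.183, with a median of 0.022 and a mean of -0.021). The falls included the Notch effectors Heyl (-0.46 ± 0.057, adjusted p = 3.05e-05), Hes1 and Hey1 and the receptors Notch1 and Notch3, and Vcam1 rose by 0.39 ± 0.093 (adjusted p = 0.00984, and 0.0817 without control arrays 4 and 6), as did Rbl2. Hes1, Hey1, Notch1, Notch3 and Rbl2 were chosen after their values were seen.

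Lists of matrix, focal adhesion and TGF-beta response genes were called lower in the Mef2c shRNA arrays. Of 33 extracellular matrix genes 12 fell and Mmp2, Col12a1 and Dcn, chosen after their values were seen, rose (14 and 4 adjusted over the list alone). The falls were led by tenascin C, Tnc (-1.09 ± 0.19 SE, adjusted p = 0.000728), and Col6a3 (-0.65 ± 0.096, adjusted p = 0.000171). For the list as a whole the adjusted p was 4.06e-05, and adjusted p = 0.07 with an estimated correlation. Of 27 focal adhesion genes 9 fell (17 adjusted over the list alone; adjusted p = 8.82e-08, and 0.022 with an estimated correlation), with the actin crosslinker Flna at -0.38 and Fhl3 at -0.36. Of 19 genes of the TGF-beta and BMP list 10 fell, including Ccn2 and Tagln (-0.80 ± 0.14, adjusted p = 0.000926), and Smad6 rose (10 and 1 adjusted over the list alone; adjusted p = 1.22e-05, and 0.027 with an estimated correlation; Smad6 chosen after its value was seen). Nuclear pore complex genes had 5 falls and 1 rise among 25 (the same adjusted over the list alone): Nup43 fell by 0.33, Nup93 by 0.29, and Nup107, Seh1l and Nup54 by 0.22, 0.19 and 0.17, while Nup214 rose by 0.18, the last 4 chosen after their values were seen. The list's adjusted p of 0.00742 became 0.189 with an estimated correlation, 0.0875 with dim genes left out and 0.0742 on renewed quantile normalization. Nuclear envelope genes had 3 falls and 1 rise among 19 (3 and 1 adjusted over the list alone; adjusted p = 0.175). The lamins Lmnb1 and Lmnb2 fell by 0.31 and 0.29, Nrm fell by 0.33, a call lost without control arrays 4 and 6 (adjusted p = 0.137), and Syne1 rose; Lmnb2 and Syne1 were chosen after their values were seen. Glycolysis and glycogen genes had 5 falls and 1 rise among 17 (8 and 2 adjusted over the list alone), with the glycogen synthase Gys1 at -0.34 and Pgk1 at -0.25. Slc2a1, Ldha and Pkm also fell and Gyg rose, chosen after their values were seen. The list's adjusted p of 0.0261 became 0.33 with an estimated correlation, 0.051 without Mef2c shRNA array 5 and 0.0509 on renewed quantile normalization.

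Lists of adipocyte markers, p53 targets and interferon response genes were called higher in the Mef2c shRNA arrays, with most members not past the test. Of 9 adipocyte markers Lpl and Cebpa rose (2 adjusted over the list alone; Cebpa, at 0.37, was chosen after its value was seen), with an adjusted p of 0.00224, and 0.0395 with an estimated correlation. Of 20 p53 targets 6 rose and Rrm2b, chosen after its value was seen, fell (7 and 2 adjusted over the list alone), with Trp53inp1 at 0.51 ± 0.080 SE and Fas at 0.34 ± 0.088 (adjusted p = 0.0171, and 0.112 without control arrays 4 and 6). The list's adjusted p was 0.00627, and adjusted p = 0.213 with an estimated correlation. Of 32 interferon response genes 5 rose (8 rises and 2 falls adjusted over the list alone), which were Rtp4 at 0.41, Isg15 at 0.39 (5.45 against 5.06, both below the receptor-gene background, so that its size is uncertain), Ifit1, Usp18 and Ifi35, the last 3 chosen after their values were seen. As a list they had an adjusted p of 0.01, which became 0.12 with an estimated correlation and 0.105 with dim genes left out. The oxidative phosphorylation list was called higher with 1 member, Sdhc (chosen after its value was seen), lower and none higher (3 rises and 1 fall adjusted over the list alone), at an adjusted p of 0.0333, and adjusted p = 0.464 with an estimated correlation. That call was lost without Mef2c shRNA array 1 (adjusted p = 0.0914) or 3 (0.135), without control array 2 (0.0632), 4 (0.0687) or 5 (0.0629), or both control arrays 4 and 6 (0.0531), and on median centring (0.0885). The NF-kB and inflammatory list had 6 rises and 2 falls among 18 (6 and 4 adjusted over the list alone; list adjusted p = 0.455), the falls being the cyclooxygenase Ptgs2 at -0.44 and Tnfaip3. The list had 0 rises and 1 fall without control arrays 4 and 6, where the Cxcl5 call was lost (adjusted p = 0.119). The chemokine Cxcl5 rose by 0.63 ± 0.17 (adjusted p = 0.0208) from 5.23, below the receptor-gene background, so that the size of the difference is uncertain. The Cxcl5 call was also lost without Mef2c shRNA array 5 (0.0514) or control array 1 (0.0528) or 6 (0.0505). In the atrophy, ubiquitin and autophagy list the ubiquitin ligase Trim63 (0.28), Fbxo31 and Map1lc3b rose among 19 (4 adjusted over the list alone; list adjusted p = 0.3). Tnfaip3 and Map1lc3b were chosen after their values were seen. The Fbxo31 call was lost without Mef2c shRNA array 1 (adjusted p = 0.0552), 5 (0.051) or 6 (0.0645) or control array 2 (0.0539), 5 (0.0599) or 6 (0.065), without control arrays 4 and 6 (0.0844), on median centring (0.0766) and in the unequal-variance test (0.0505). It was also lost with the replicate number as a block. Of 10 reference genes Gusb (-0.30), Hprt (-0.20), Actb (-0.19) and Tbp (-0.17) fell (4 adjusted over the list alone), the last pair chosen after their values were seen. Camera gave the list an adjusted p of 0.0593, and 0.0475 without Mef2c shRNA array 1 and 0.0314 on median centring. The Hprt call was lost without Mef2c shRNA array 5 (adjusted p = 0.0558) or 6 (0.052), or control array 1 (0.058) or 4 (0.0566), or both control arrays 4 and 6 (0.119). Markers of smooth muscle (adjusted p = 0.175; Tagln and Cnn1 fell), osteoblasts (0.674; Phex rose, Dmp1 fell), fibroblasts (0.917; Dcn rose, Col1a1 fell), neural cells (0.54; Tubb3 fell) and macrophages (0.827; none called) did not pass. Their counts were the same adjusted over the list alone, and the genes were chosen after their values were seen. The neural list had a median of 0.032 and a mean of -0.073.

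**Figure D3:**
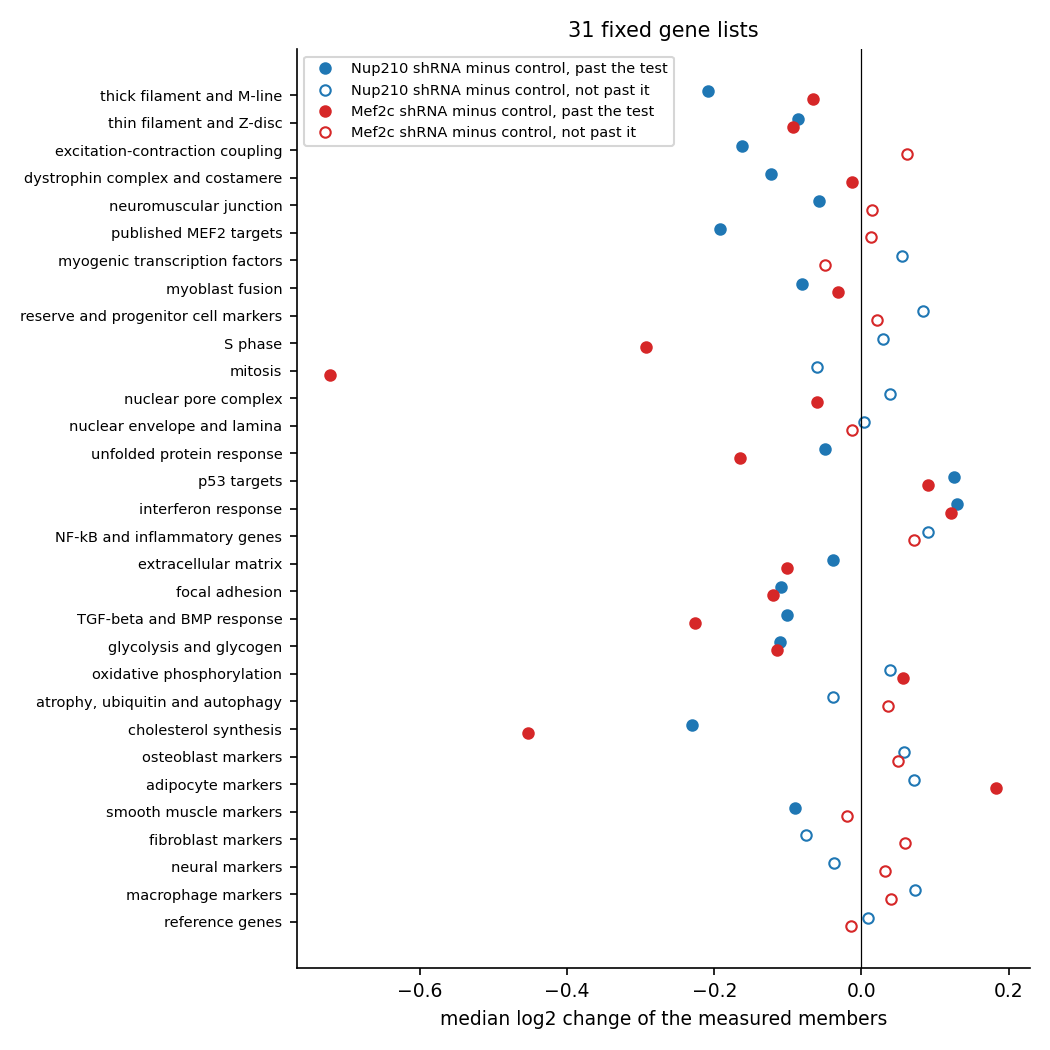
For each of 31 gene lists on the vertical axis, points give the median log2 change of its measured members in the Nup210 shRNA arrays (blue) and the Mef2c shRNA arrays (red) against control; filled points passed camera's test with its preset correlation. Mitosis lies at -0.72 in red, and cholesterol synthesis at -0.23 in blue and -0.45 in red.

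Set directly against each other, the shRNA groups differed in the cell cycle and in calcium handling, among other lists. Of the mitosis genes 24 of 27 were higher in the Nup210 than in the Mef2c shRNA arrays and none lower (27 adjusted over the list alone; median 0.67, camera adjusted p = 1.19e-27, and adjusted p = 0.0557 with an estimated correlation). So were 21 of 26 S phase genes (23 adjusted over the list alone; adjusted p = 3.35e-19, and adjusted p = 0.0557 with an estimated correlation). Of the excitation-contraction coupling genes 14 of 24 were lower in the Nup210 shRNA arrays and none higher (15 lower and 1 higher adjusted over the list alone; adjusted p = 2.19e-08, and adjusted p = 0.0991 with an estimated correlation), with Hrc at -0.63. Published MEF2 targets had 9 members lower and 2 higher, Jun and Myog, of 25 (10 and 3 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.562 with an estimated correlation). Of 12 neuromuscular junction genes Chrng, Chrnd, Rapsn and Chrnb1 were lower (4 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.101 with an estimated correlation). Myogenic transcription factors had 8 members higher of 18, with Myf6 at 0.74 and Myog at 0.17 (8 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.12 with an estimated correlation). The unfolded protein response had 10 higher and 2 lower, Xbp1 and Dnajb11, of 24 (14 and 2 adjusted over the list alone; adjusted p = 6.48e-05, and adjusted p = 0.161 with an estimated correlation). Cholesterol synthesis had 7 higher and 2 lower, Ebp and Dhcr7, of 17 (9 and 2 adjusted over the list alone; adjusted p = 0.00136, and adjusted p = 0.562 with an estimated correlation). Among 25 nuclear pore genes Nup43, Nup93, Aaas, Nup54 and Rae1 were higher and Nup214, Gle1 and Nup50 lower (8 and 3 adjusted over the list alone; adjusted p = 0.0122, and adjusted p = 0.272 with an estimated correlation). Of 9 adipocyte markers Lpl and Cebpa were lower (2 adjusted over the list alone; adjusted p = 0.0339, and adjusted p = 0.161 with an estimated correlation). Members named in these lists were chosen after their values were seen. The remaining 21 lists did not pass. Of these, thick filament genes passed on renewed quantile normalization (0.0486) and without Nup210 shRNA array 1 (0.0475) or 6 (0.0295) or Mef2c shRNA array 5 (0.0268). Reserve markers passed without the same arrays (0.0475, 0.0295 and 0.0309), and extracellular matrix genes without Nup210 shRNA arrays 2, 4 and 5 (0.00692). For thin filament genes the median of -0.039 and the mean of 0.0024 had opposite signs. With dim genes left out the calls of myogenic transcription factors (0.0826) and nuclear pore genes (0.0967) were lost. The adipocyte call was lost without Nup210 shRNA array 1 (adjusted p = 0.0501) or 2 (0.0543), or Mef2c shRNA array 3 (0.066) or 5 (0.0527). Without Nup210 shRNA arrays 2, 4 and 5 the calls of MEF2 targets (adjusted p = 0.0761), myogenic transcription factors (0.0572), nuclear pore genes (0.0671) and adipocyte markers (0.0632) were lost. Large differences included Mef2c at 2.39 ± 0.10 SE, Slc30a5 at 1.67 ± 0.055 and Igf2 at 1.503 ± 0.097, higher in the Nup210 shRNA arrays. Mcpt1 was also called higher there, at 6.99 against 4.91, the latter below the receptor-gene background, so that the size of the difference is uncertain. Lower were Fam180a at -1.49 ± 0.24, Grhl3 at -1.46 ± 0.17, Dap at -1.43 ± 0.066 and the surface glycoprotein Cd24a at -1.25 ± 0.15. Nup210 itself differed by -0.23 ± 0.064 between these groups (limma adjusted p = 0.0178, and 0.174 without Nup210 shRNA arrays 2, 4 and 5). In all, 1575 genes were higher and 1538 lower in the Nup210 than in the Mef2c shRNA arrays, and without Nup210 shRNA arrays 2, 4 and 5 the lower count was 995, with 1869 of the 3113 calls kept.

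Some genes changed in both shRNA groups. Car2 rose by 0.91 and 0.89 on the log2 scale in the Nup210 and Mef2c shRNA arrays, the growth factor Hgf by 0.65 and 0.74, the adrenomedullin and CGRP receptor Calcrl by 0.64 and 0.78, Hpgd by 0.98 and 0.62, and Trp53inp1 by 0.55 and 0.51. The cathepsin Ctsw fell by 0.88 and 0.89, the lipocalin Apod by 0.71 and 0.94 (the latter to 5.47, the level of the receptor-gene background), the retinoic acid binding protein Crabp2 by 0.65 and 0.78, and the growth factor Pdgfb by 0.66 and 0.64, besides Casq1 with the losses of its call given above. Opposite changes included the Notch ligand Jag1 (0.38 and -0.35), Stard3nl (0.36 and -0.50) and the ephrin Efnb2 (0.27 and -0.51), higher in the Nup210 and lower in the Mef2c shRNA arrays, and the AMP deaminase Ampd1 (-0.52 and 0.47), Rundc3a (-0.42 and 0.55) and Gpr20 (-0.77 and 0.39), the other way round. The Efnb2 call in the Nup210 shRNA arrays was lost without Nup210 shRNA array 1, 2, 4 or 6, Mef2c shRNA array 1, 2, 3, 4 or 5, or control array 1, 2, 3, 4 or 5, with adjusted p from 0.0523 to 0.105. Without Nup210 shRNA arrays 2, 4 and 5 the calls in the Nup210 shRNA arrays of Hgf (adjusted p = 0.0881), Ctsw (0.101), Apod (0.149), Crabp2 (0.179), Jag1 (0.0782), Stard3nl (0.0501), Efnb2 (0.148) and Rundc3a (0.0628) were lost. Without control arrays 4 and 6 the Mef2c shRNA call of Jag1 was lost (0.0611). In all, 183 genes rose in both comparisons and 290 fell in both, while 84 moved in opposite directions, 27 of them higher in the Nup210 shRNA arrays. Independent lists of these sizes would share 29.4, 72.7 and 92.6 genes. Unchanged groups simulated against the same controls shared 0 genes in all 100 simulations, which leaves out the effects and so gives no value to set the counts against. With the controls split 3 and 3, so that no array served both comparisons, the 20 splits gave medians of 44.5, 97 and 30.5 genes, where independent lists of the sizes called in each split would share 6.3, 24.2 and 24.9. Across genes, which are not independent replicates, the log2 changes correlated at 0.394 against a simulated median of 0.511 for unchanged groups sharing the controls, and at 0.174 with split controls. Their covariance was 0.00941 against a simulated mean of 0.0053, a difference of 0.00411. The count of shared falls was 193 without control array 6, and the count of opposite changes 54 without control array 3 and 53 without control array 4. Without Nup210 shRNA arrays 2, 4 and 5 the 3 counts were 58, 105 and 40, and without control arrays 4 and 6 they were 82, 127 and 40; on median centring 100 genes rose in both. Other settings gave more. With dim genes left out the 3 counts were 334, 485 and 191, and with the replicate number as a block 269, 456 and 152. With a trended robust prior 138 genes moved in opposite directions. The values for independent lists above belong to the calls of the first fit and not to these settings.

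**Figure D4:**
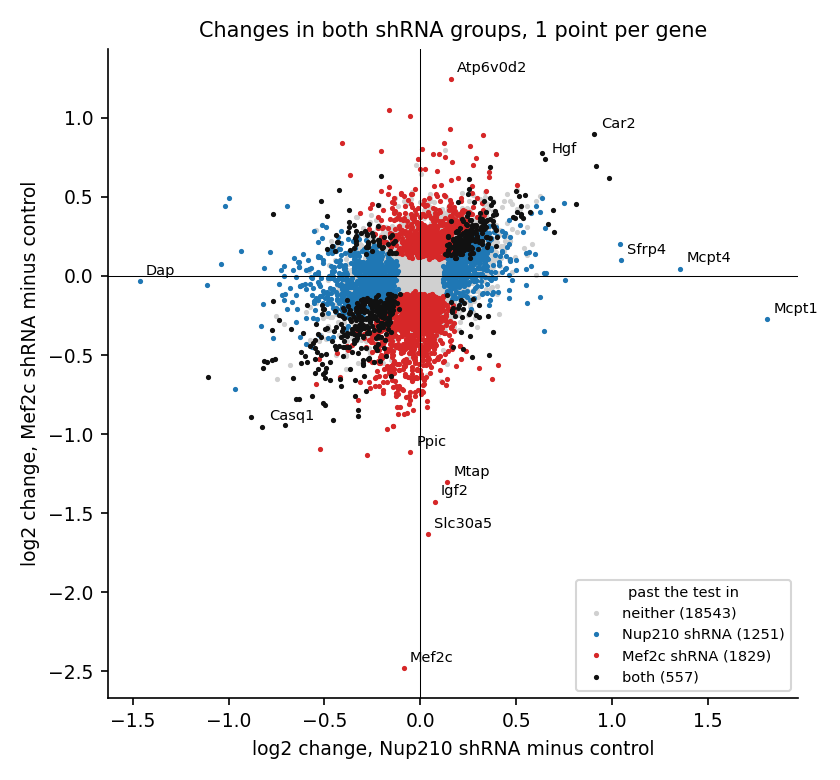
Each point is a gene, with its log2 change in the Nup210 shRNA arrays on the horizontal axis and in the Mef2c shRNA arrays on the vertical axis, both against control; black points passed the test in both comparisons (557 genes). Mef2c lies at -2.48 on the vertical axis and Mcpt1 at 1.81 on the horizontal axis, and Car2 lies at 0.91 and 0.89.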

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

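The tests of why cell cycle, cholesterol synthesis and single-group genes changed were all chosen after those results had been seen; the regroupings of arrays were fixed beforehand. A gap test of the highest or lowest of 6 arrays was run on 426 groups of values, from 111 named genes and 31 list means in 3 shRNA groups. It marked 14, where chance alone marks about 1 in 20, or 21.3.

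In the control arrays, Col3a1 was high in array 3 (10.73 against 10.55 to 10.58), Jag1 was low in array 2 (7.25 against 7.413 to 7.497), Mcpt1 was low in array 1 (4.76 against 5.12 to 5.33), Nup210 was low in array 6 (5.57 against 5.75 to 5.81), and the mean of the myoblast fusion list was low in array 3 (-0.030 against 0.0018 to 0.016). In the Mef2c shRNA arrays, array 5 was low for Dok7 (7.67 against 7.96 to 8.12), Jag1 (6.69 against 7.04 to 7.21), Jam2 (9.69 against 9.88 to 9.96) and Mef2c itself (7.51 against 7.88 to 8.08). Array 5 also had the lowest Mef2c value of the Nup210 shRNA arrays (10.08) and of the controls (10.10). Array 6 of the Mef2c shRNA group was high for Myf6 (5.81 against 5.40 to 5.55) and Sfrp4 was low there (6.06 against 6.46 to 6.64), as given in log2 levels. Olfr823 was low in Mef2c shRNA array 6 (2.25 against 2.82 to 3.09). In the Nup210 shRNA arrays, Ptgs2 was low in array 3 (9.48 against 9.66 to 9.76) and the mean of the macrophage markers was high in array 4 (0.21 against -0.06 to 0.04). Of 17824 probe sets without a single gene symbol, which no comparison above used, 47 passed limma's test in the Nup210 shRNA arrays and 124 in the Mef2c shRNA arrays against control.

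Chance in the grouping of arrays was tested by refitting 100 splits of the 12 arrays of each comparison, the real split included. The real split was the only 1 of 100 to call as many genes in all 3 comparisons. It called 1809 genes for Nup210 against control shRNA where the highest other split called 1, 2386 for Mef2c against control shRNA where the highest other called 289, and 3113 for Nup210 against Mef2c shRNA where the highest other called 433. The other splits mix the real groups, so any difference that goes with the groups, a batch included, would give this outcome. The counts thus speak to a random grouping of these arrays and not to its cause.

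Mitosis and S phase genes fell in the Mef2c shRNA arrays. That the pattern rests on the high cell cycle levels of control arrays 4 and 6 is argued against, since the mitosis median was -0.61 without them and -0.72 with them. A lower share of undifferentiated cells may contribute: the reserve and progenitor markers had a median change of 0.0216, with bootstrap bounds from -0.18 to 0.06 over members that moved both ways, which neither requires nor excludes it. Loss of cycling cells in the culture and lower expression of these genes per cell cannot be told apart in bulk RNA, and the biological effect of the Mef2c shRNA stays open as a hypothesis.

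Cholesterol synthesis genes fell in both shRNA groups, but for Nup210 shRNA the list did not pass with an estimated correlation (adjusted p = 0.112) and 1 gene was called without arrays 2, 4 and 5. That a few of the shared control arrays set the pattern is argued against. Over 20 splits of the controls and both groups, the list's median change stayed between -0.48 and -0.20, its highest value being -0.1982. A deviation common to all control arrays would enter every split alike, so the splits cannot test it and it stays open. An excess of cell sterol, which lowers these genes and activates the nuclear receptor LXR, is a candidate that the values leave open in the Mef2c shRNA arrays. There 8 measured LXR target genes had a median change of 0.22 (bounds 0.12 to 0.67), 4 of them called higher. A sterol excess is argued against in the Nup210 shRNA arrays, where the same genes had a median of -0.15 and 3 were called lower. Of the targets 5 had been seen before the test was chosen, and sterol was not measured. The list leaves out fatty acid synthesis genes such as Scd1 and Fasn, which fell in the Mef2c shRNA arrays (log2 changes of -0.30 and -0.38). Of the fatty acid synthesis genes measured, 8 of 8 were called lower there (median -0.34), against the direction of the listed targets. The median rise there thus holds for the 8 genes of the list.

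Many large falls belonged to a single shRNA group, such as Dap in the Nup210 and Slc30a5, Mtap and Ppic in the Mef2c shRNA arrays, while others, such as Hephl1 and Casq1, were called in both. Silencing of unintended transcripts by a hairpin could contribute, but the share of falls does not decide it: of 178 genes changed at least 1.5-fold in a comparison with control and differing between the groups in that direction 79.8% fell, against 68.6% of the 70 other changes of that size. Genes also called in the other group were not left out of the 178. Fads2, at -0.33 in the Nup210 and -0.85 in the Mef2c shRNA arrays, is an example. Silencing by a hairpin cannot be told apart from effects of the intended target, since hairpin sequences were not used here and each target has 1 label. Probe sets that read another transcript are a further candidate explanation, which the values leave open: counted once per gene, a unit chosen after a count per probe set had been seen, the other probe sets of 38.5% of 13 such genes (5 genes) all changed in the same direction at an unadjusted p under 0.05, and those of 12 had the same sign.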

How the results depend on the processing

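The fits without the 3 arrays of lowest weight and without control arrays 4 and 6 were chosen after seeing the data; all other alternatives were planned. No called result reversed in any setting, while medians near 0 of lists that were not called changed sign in some. Over all settings 4269 of 4426 named-gene values and 2307 of 2415 list tests kept their side of the threshold. Most named genes were picked as large changes among the first fit's calls, and most settings left out a single array, which favours such a result. Over all genes fewer calls held. For Nup210 shRNA 1168 of 1809 calls were kept in the unequal-variance test and 1047 without control arrays 4 and 6. For Mef2c shRNA 1981 and 1360 of 2386 were kept. The cause of the changes below was not tested, except that stricter thresholds by construction call fewer genes, and that a filter changes how many genes are tested. Below, counts of genes are higher then lower for Nup210 against control, Mef2c against control and Nup210 against Mef2c shRNA. At an adjusted p under 0.01 they were 269 and 635, 423 and 879, 971 and 928, with 60 higher in both, 112 lower in both and 28 opposite. With at least 1.5-fold they were 24 and 67, 34 and 124, 99 and 109, with 5, 7 and 0. Median centring gave 395 higher for Nup210 and 625 for Mef2c shRNA and 100 higher in both. Leaving out genes below the median level gave 334 higher in both, 485 lower in both, 191 opposite and 1 list higher for Nup210 shRNA, and ended 10 list calls, which the results give beside each list. A trended robust prior gave 138 opposite changes. Renewed quantile normalization called 8 lists lower for Mef2c shRNA. With an estimated correlation 0 lists were higher and 0 lower for Nup210 shRNA, 1 and 6 for Mef2c shRNA, and 0 and 0 between them. Without the 3 arrays of lowest weight 153 rose and 410 fell for Nup210 shRNA, 995 were lower between the groups, 58, 105 and 40 were shared or opposite, and 2 lists were lower between the groups. Without control arrays 4 and 6 the counts were 379 and 724 for Nup210 and 537 and 883 for Mef2c shRNA, with 82, 127 and 40. Leaving out each of the 18 arrays in turn moved the opposite changes from 53 to 87, the shared falls from 193 to 300 and the shared rises from 124 to 192, and ended the call of 11 named genes and 7 lists in at least 1 omission. Of 138 named-gene calls, 32 were lost without the 3 arrays of lowest weight, 19 without control arrays 4 and 6, and 20 in the unequal-variance test, with adjusted p from 0.0505 to 0.162. Those 20 were Fam180a, Tnnt1, Casq1, Dok7, Chrnb1, Aaas, Gle1, Col6a3, Cnn1, Tagln, Insig1, Efnb2 and Apod for Nup210 shRNA, Olfr823, Mef2d, Tcap, Myoz2, Vcam1 and Fbxo31 for Mef2c shRNA, and Nup210 between the groups. The 32 were Grhl3, Fam180a, Mef2d, Myod1, Tnnt1, Casq1, Sgcd, Lama2, Dok7, Chrnb1, Dock5, Aaas, Gle1, Lmnb2, Zmat3, Col6a3, Itga6, Tes, Cnn1, Tagln, Pygm, Trim63, Insig1, Hgf, Stard3nl, Jag1, Efnb2, Ctsw, Apod, Crabp2 and Rundc3a for Nup210 shRNA and Nup210 between the groups (0.0501 to 0.391). The 19 were Mef2d, Dok7, Chrnb1, Col6a3, Itga6, Tes, Cnn1, Tagln and Insig1 for Nup210 shRNA, and Mef2d, Tcap, Myoz2, Vcam1, Nrm, Fas, Cxcl5, Fbxo31, Hprt and Jag1 for Mef2c shRNA (0.0516 to 0.201). With only the compared groups in the fit, Chrnb1, Gle1, Cnn1 and Efnb2 for Nup210 shRNA and Mef2d for Mef2c shRNA lost their calls. Others lost were Gle1 on renewed quantile normalization (0.0715), Efnb2 on median centring (0.0823), Tes with probe sets averaged (0.212) and Tagln with array weights (0.0512), all for Nup210 shRNA.

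The groups share replicate numbers, which were not taken to pair the samples, since the labels name no shared day and not every pair correlated above 0.1. Deviations of same-numbered arrays correlated at -0.18 to 0.22, with a median of 0.063 against -0.014 for arrays of other numbers. Of 18 pairs 6 exceeded 0.1. Of 18 arrays, 12 correlated best with their own number, although most arrays of the other groups bore other numbers. For the thick filament list, array 5 was the lowest in all 3 groups (-0.39, -0.28 and -0.12 from the control mean for Nup210, Mef2c and control shRNA). The thin filament and MEF2 target lists were also lowest in array 5 of each group. Same-numbered arrays were thus more alike than others. A replicate effect, such as a shared day, stays open, and the main fit leaves it out. With the replicate number as a block, 811 genes rose and 1410 fell for Nup210 shRNA, 1221 and 1641 for Mef2c shRNA, and 1742 and 1786 between them, with 269 higher in both, 456 lower in both and 152 opposite. With this block, for Mef2c shRNA Myog was called (adjusted p = 0.0139) and Fbxo31 was not (0.0532), and between the groups the thick filament (0.0302) and reserve marker lists (0.0401) were called. Signal over background limits dim genes: 58.7% of genes lay above the 95th percentile of receptor genes, and Nup210 lay close to it.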

Other observations

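All gene groups in this part were chosen after values of some of their members had been seen; the test of neighbouring genes was chosen before its result. Fatty acid synthesis genes fell in the Mef2c shRNA arrays: 8 of 8 were called lower, with a median log2 change of -0.34 (camera adjusted p = 3.3e-14 over the 4 groups tested, and 0.00209 with an estimated correlation). They included the desaturase Fads2 (-0.85 ± 0.075 SE), the elongase Elovl6 (-0.57 ± 0.074) and the fatty acid synthase Fasn (-0.38 ± 0.043). In the Nup210 shRNA arrays 3 of the 8, Scd1, Fads1 and Fads2, fell (adjusted p = 0.000512, and 0.0751 with an estimated correlation). The LXR targets Abca1, a cholesterol exporter, and Abcg1 rose by 0.67 ± 0.082 and 0.25 ± 0.068 in the Mef2c shRNA arrays, as did Lpl and Pltp (0.19), while the phospholipid transfer protein Pltp (-0.46 ± 0.053), Mylip (-0.37 ± 0.051) and Lpcat3 (-0.34 ± 0.051) fell in the Nup210 shRNA arrays. Of the 8 targets 7 were lower in the Nup210 than in the Mef2c shRNA arrays (median difference -0.48, adjusted p = 3.84e-11, and 0.000321 with an estimated correlation), and 5 fatty acid synthesis genes were higher (adjusted p = 8.81e-07, and 0.024 with an estimated correlation).

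Imprinted genes moved both ways in the Mef2c shRNA arrays: Igf2, Cdkn1c (-0.64 ± 0.057), Mest (-0.43 ± 0.077) and Igf2r (-0.18 ± 0.040) fell, and Zim1 (0.77 ± 0.14), Peg3 (0.45 ± 0.060) and Usp29 (0.26 ± 0.083, at 4.93, below the receptor-gene background, so that its size is uncertain), neighbours of each other, rose. The 18 measured imprinted genes did not move as a group (adjusted p = 0.425, downward by camera against a median of 0.040), and in the Nup210 shRNA arrays Igf2r alone was called (0.31 ± 0.040). Beyond Mcpt1 and Mcpt4, 0 of 10 other mast cell genes, among them Cpa3, Kit and Cma1, were called in the Nup210 shRNA arrays. As a group these passed upward (adjusted p = 0.0347), and not with an estimated correlation (0.0751), with 9 of the 10 below the receptor-gene background. Their median change was 0.16 there and 0.15 in the Mef2c shRNA arrays, where the group did not pass (camera adjusted p = 0.192). It did not differ between the shRNA groups (camera adjusted p = 0.731), so this rise does not set the Nup210 shRNA arrays apart. Of 11 signalling genes looked at, Myc and Bmp4 were among those that differed between the groups, while Hgf (adjusted p of the difference = 0.778), Id3 (0.592) and Dll1 (0.0732) did not pass. Myc changed by 0.35 ± 0.051 in the Nup210 and -0.26 ± 0.051 in the Mef2c shRNA arrays (adjusted p of the difference = 2.45e-07), and Bmp4 by -0.49 ± 0.11 and 0.31 ± 0.11 (adjusted p of the difference = 3.67e-05), the latter not called in the Mef2c shRNA arrays.

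Neighbouring genes were called in the same direction more often than shuffling gives, a hypothesis of shared chromosomal neighbourhood. Among 18965 adjacent pairs of protein-coding genes, in the order of assembly GRCm38.p6, 121 pairs of differently named families shared a direction in the Nup210 shRNA arrays, against 83 to 119 in the middle 95% of 1000 shuffles within expression level (one-sided permutation p = 0.018). In the Mef2c shRNA arrays there were 215 pairs against 143 to 189 (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). The excess may include overlapping transcripts read by shared probes, which was not tested.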
